A study of Zea mays with 8 samples.

How the data were processed

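RNA sequencing measured gene expression in kernels of the maize inbred line B73. The aleurone layer of the endosperm and the starchy endosperm beneath it were sampled at 18 and 22 days after pollination (DAP). Each of the 4 combinations of tissue and age had 2 biological replicates, which gave 8 libraries. Per the labels' protocols, kernels came from replicate greenhouse plants, were frozen, and were peeled mechanically after thawing and rinsed in water. RNA integrity was checked in 1 library of each replicate pair and libraries followed the TruSeq RNA protocol, per the labels' protocols.

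Per the submitters' processing notes, reads were processed with FastQC, Bowtie2 2.2.3, SAMtools and RSEM 1.2.15 against the genome build B73 RefGen_v3. The gene annotation and the strand setting are not given in the sources used here. Per the file headers, the authors deposited RSEM expected counts for each gene and library, which are estimated read counts without scaling. The same deposited tables give TPM, a length-corrected share of transcripts, which RSEM computes from effective gene lengths, per the file headers. A further deposited table lists the mean TPM of each tissue and age, per the labels. Gene lengths in the deposited tables were used for 1 check.

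Each replicate table listed 39475 gene IDs. They were matched to names in a reference table of the assembly Zm-B73-REFERENCE-NAM-5.0 through symbols and synonyms, and no coordinates were taken from it. Among its entries 18908 IDs (47.9%) were found, 2600 of them with a name other than a locus number or clone, and 521 IDs were paired with 2 or more reference genes. Genes are called here by that name, or by their ID where the table gave none.

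Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 19058 genes, and library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model of 4 group means was fitted to all 8 libraries, so that the groups shared 1 estimate of the spread. The 5 contrasts were aleurone against starchy endosperm at each age, 22 against 18 DAP in each tissue, and the interaction, the change of the tissue difference between the ages. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from this edgeR quasi-likelihood test unless another tool is named, and they measure the spread between these samples only. Standard errors (SE) of log2 fold changes were taken from the F statistic.

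Gene lists for the endosperm and for other kernel tissues were fixed before the data were examined, as were the contrasts, the test, the rule for naming genes and the alternatives not described as added. Of 224 symbols in these lists, 86 were not found and 11 were found on several genes and left out. Families were matched by name patterns written after the names of the reference table were seen and before any expression values were compared. These patterns also added the lists of jasmonate and of glycolysis and fermentation genes. Of the 32 lists with members, 25 had the 5 tested members needed. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Alternatives were camera with an estimated correlation and fry, which tests a list against no change and not against the other genes. Where the calls in a list are counted, those over all tested genes are given beside those adjusted over the list alone.

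Genes were named by a rule. For each contrast between groups it took the 6 called genes with the largest positive and the 6 with the largest negative log2 fold change, if named, without overlap between the groups and with a mean of at least 20 TPM in the higher group. For the interaction it took 4 in each direction. It added up to 4 members of each tested list, by adjusted p, with at least 5 TPM in a group, all classical regulators of aleurone fate and endosperm filling, and the 5 genes of highest mean TPM per group. Further list members are named where a count of a list is spelled out.

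Where a gene had no count in a group, its fold is a lower bound against 3 counts over the group. With 1 to 3 counts, a ratio of TMM-scaled counts with its exact 95% binomial (Clopper-Pearson) interval is given in place of the fitted value, which depends on a prior count. Reads are not independent molecules, so intervals and floors cover counting error only. For the shallowest library, starchy endosperm at 22 DAP replicate 1, 3 counts were 2.26 TMM-scaled CPM (library-scaled counts), and for the deepest scaled library, aleurone at 22 DAP replicate 2, they were 0.282.

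The labels do not say whether libraries with the same replicate number came from the same plants. The differences between replicates correlated across genes in all 6 pairs of groups (Pearson r from 0.19 to 0.41 over 19058 genes, and from 0.38 to 0.77 over 2717 genes above a mean log2 CPM of 5). The replicate number also went with depth and detected genes. A fit with the replicate number as a block is therefore given beside results it moves. This fit was also chosen before any expression value was read. Each number holds 1 library per group. A test within a number was not made, and values per number are descriptive.

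The test was tried on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold among the more abundant genes. They were drawn from each gene's mean over all libraries, the scaled library sizes and a dispersion set by abundance alone. At 18 DAP the tissue contrast recovered 5% and 45% of them over 17842 genes, and at 22 DAP 5% and 38% over 17742 genes. The age contrast recovered 6% and 49% over 17791 genes in aleurone, and 3% and 44% over 17785 genes in starchy endosperm. The interaction recovered 2% and 20% over 17654 genes. At most 3 unchanged genes were called in any of these runs. The simulation held no other tissue difference, no gene-specific spread and no effect of the replicate number, so these rates need not hold for the samples.

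Alternatives were size factors of DESeq2, library size only, upper quartile factors, and scaling without zeins and the 20 most abundant genes. Others were no filter beyond a count above 0, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma on log2(TPM + 1) and on log2(TPM + 0.1), only the libraries compared, the replicate block over all libraries or within each age, a minimum fold change of 1.5 (glmTreat), and leaving out each library in turn. Fits without both starchy endosperm libraries of the other age were added after the data were seen. With 2 libraries per group, no test for outlying libraries was made. Figures were drawn with Python 3.11.15.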

Results

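To describe how the aleurone, the outer cell layer of the endosperm, differed from the starchy endosperm beneath it, gene expression was compared in kernels of the maize line B73. Both tissues were sampled at 18 and 22 days after pollination (DAP), with 2 biological replicates in each of the 4 groups and 8 libraries in all. Total counts were 2944736 and 5991344 in aleurone at 18 DAP (replicates 1 and 2), 3074186 and 7001758 in aleurone at 22 DAP, 3185962 and 11529170 in starchy endosperm at 18 DAP, and 2473036 and 6767595 in starchy endosperm at 22 DAP. Although deeper, the replicate 2 libraries held fewer detected genes in every group: 20663 against 22786, 20134 against 23154, 14186 against 18172, and 9335 against 16720, in the same order. After filtering, 19058 genes were tested. The p-values below measure the spread between these libraries, and intervals and lower bounds on ratios cover counting error only.

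Zeins, the seed storage proteins of maize, dominated the starchy endosperm. The 26 zein genes found by name took 58.1 ± 2.46% of counts at 18 DAP and 60.9 ± 2.42% at 22 DAP (mean ± SD of 2 libraries), against 8.46 ± 0.731% and 10.9 ± 1.22% in aleurone. Genes without a name could not enter this list, among them the abundant AF546188.1_FG005 and AF546188.1_FG007. These 2 held 7.47% and 6.16% of TPM in starchy endosperm at 18 DAP, and 8.57% and 6.67% at 22 DAP. Whether they encode zeins was not checked, so the shares cover the named zeins only. The alpha-zein z1A1_3 (GRMZM2G059620) alone reached 138278 ± 13813 TPM and 158726 ± 14983 TPM in starchy endosperm. It was also the most abundant named gene of the aleurone peels, at 23045 ± 3248 and 27287 ± 4941 TPM. Next in aleurone at 18 DAP came plt1 (GRMZM2G101958), a phospholipid transfer protein, at 21335 ± 9474 TPM, higher than in starchy endosperm by a log2 fold change of 8.53 (SE 0.83, adjusted p = 0.00217). The oleosins and other oil body genes summed to 10009 ± 5893 TPM in aleurone and 15.8 ± 9.16 TPM in starchy endosperm at 18 DAP, and to 11332 ± 8718 and 12.4 ± 3.18 TPM at 22 DAP.

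Markers of most other kernel tissues were low in all groups. Genes of the basal transfer layer summed to 10.2 ± 3.89 TPM in aleurone and 1.60 ± 2.26 TPM in starchy endosperm at 18 DAP, and to 12.6 ± 10.9 and 16.3 ± 1.12 TPM at 22 DAP. Embryo genes summed to 20.6 ± 4.31, 7.01 ± 1.2, 2.74 ± 1.44 and 2.35 ± 1.94 TPM in aleurone at 18 and 22 DAP and starchy endosperm at 18 and 22 DAP. Photosynthesis genes had a mean sum under 5 TPM in every group, with up to 8.36 TPM in a single library. Floral regulators, listed as markers of the maternal pericarp, summed to 53.9 ± 3.72 and 130 ± 18.1 TPM in aleurone and to 10.6 ± 2.43 and 5.18 ± 7.33 TPM in starchy endosperm. Whether they are specific to the pericarp was not tested.

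**Figure D1:**
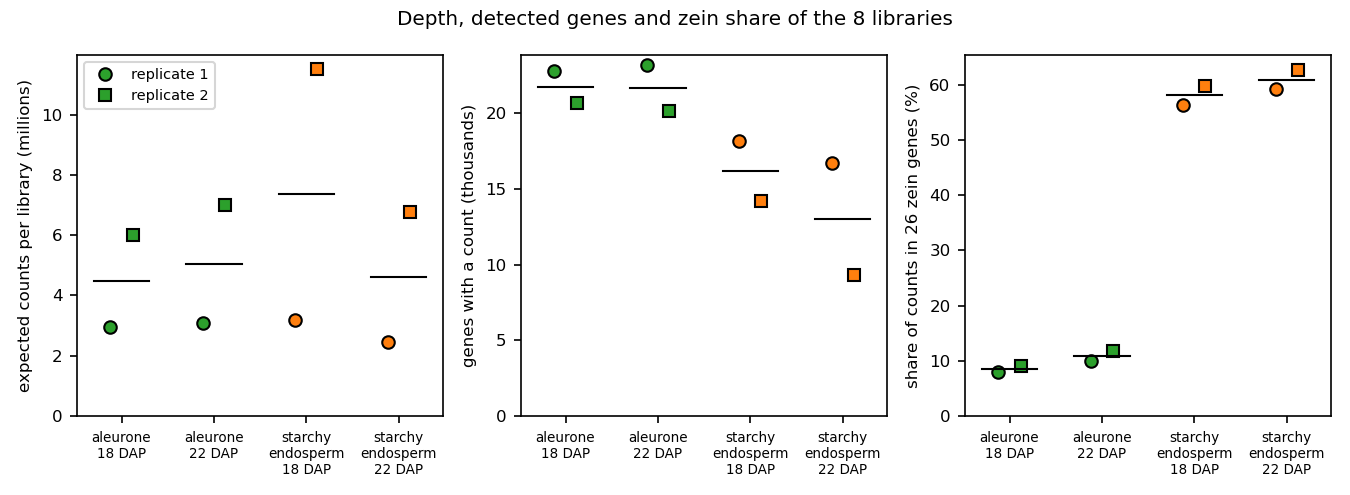
Total counts, detected genes and the share of counts from the zein genes found by name (percent) for each of the 8 libraries, by tissue and age. Each point is 1 library and each line is the group mean, for example 8.46% and 58.1% zein counts in aleurone and starchy endosperm at 18 DAP.

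To assess which genes separated the tissues at 18 DAP, aleurone was compared with starchy endosperm. Genes of oil storage were higher in aleurone: ole1 (GRMZM2G337229) and ole17 (GRMZM2G480954), which encode oleosins of the oil body surface, by a log2 fold change of 7.46 (SE 0.98, adjusted p = 0.00777) and 8.66 (SE 1.14, adjusted p = 0.00777). In TPM they were 4613 ± 2481 and 2857 ± 1996 in aleurone. A further oleosin (GRMZM2G333069) had no count in starchy endosperm and was at least 572-fold higher (adjusted p = 0.00556). The starch genes sh2 (GRMZM2G429899) and bt2 (GRMZM2G068506), which encode the subunits of ADP-glucose pyrophosphorylase, were lower in aleurone, at log2 fold changes of -5.03 (SE 0.55, adjusted p = 0.00334) and -5.20 (SE 0.66, adjusted p = 0.00729). Of the sucrose synthase genes, sh1 (GRMZM2G089713) was lower in aleurone (-4.70, SE 0.48, adjusted p = 0.00234), sus1 (GRMZM2G152908) was higher (6.85, SE 0.61, adjusted p = 0.00189) and sus2 (GRMZM2G318780) was not called (2.37, adjusted p = 0.216).

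At this age 395 genes were called by the edgeR quasi-likelihood test, 230 higher and 165 lower in aleurone. All of them had the same sign in each replicate number, which their selection from the same libraries favors. Over all tested genes, the tissue differences of the replicate numbers correlated at r = 0.67. With the replicate number as a block, 808 were called (359 higher and 449 lower), with library size only 1332 (1281 and 51) and with upper quartile factors 593 (283 and 310). The count fell to 47 without starchy endosperm at 18 DAP replicate 2, to 142 without aleurone at 18 DAP replicate 2 and to 170 without starchy endosperm at 18 DAP replicate 1. It rose to 1649 and 1617 without starchy endosperm at 22 DAP replicate 1 or 2, and was 1498 without both.

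Genes absent or nearly absent from starchy endosperm led the aleurone side. Lower bounds on the ratio were 191-fold for dxs2 (GRMZM2G493395), an enzyme of the plastid isoprenoid pathway (adjusted p = 0.0248), and 155-fold for HDZIV8_OCL8 (GRMZM2G122897), a homeodomain transcription factor of outer cell layers (adjusted p = 0.0104). They were 131-fold for vp1 (GRMZM2G133398), a transcription factor of the abscisic acid response (adjusted p = 0.0409), and 391-fold and 325-fold for a pair of genes named ZCN10 (GRMZM2G152689 and GRMZM2G059358; adjusted p = 0.0301 and 0.0282). Zlp (GRMZM2G374971), a zeamatin-like protein, had a ratio of 1127 (95% interval 312 to 9306, adjusted p = 0.0117). Of the 44 named genes, 14 stayed called without starchy endosperm at 18 DAP replicate 2, and ole1 (adjusted p = 0.0967), ole17 (0.116), the further oleosin (0.0700), Zlp (0.186) and vp1 (0.274) did not. The 14 were sus1, sh1, sh2, bt2, ss1, gpc3, gpc4, fl3 and 6 zeins, and they were called without any 1 library.

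The fixed gene lists described these sides further. Of 26 zeins, 20 were lower in aleurone, 0 were higher and 6 were not called, or 24 lower when adjusted over the list alone (camera adjusted p = 4.11e-72; adjusted p = 0.0220 with an estimated correlation, and 0.220 with that and the replicate block). The median zein log2 fold change was -4.48, with fl2 (GRMZM2G397687) at -4.61 (SE 0.43, adjusted p = 0.00196) and the gamma-zein gz50 (GRMZM2G138689) at -4.87 (SE 0.49, adjusted p = 0.00234). With library size only as the scaling, the median was -2.82. Of 21 starch synthesis genes, 10 were lower, 1 was higher (sus1) and 10 were not called, or 11 lower and 4 higher over the list alone (camera adjusted p = 7.04e-09; adjusted p = 0.161 with an estimated correlation). Besides sh1, sh2, bt2 and the starch synthase ss1 (GRMZM2G129451; -4.30, SE 0.50), the 10 were bt1, pho1, zpu1, sugary2, ae1 and du1. The waxy gene wx1 (GRMZM2G024993), a granule-bound starch synthase, was at -2.67 (SE 0.77, adjusted p = 0.137).

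Oil body genes were the strongest list on the other side, with 5 of 6 higher in aleurone, 0 lower and 1 not called, or 6 higher over the list alone (camera adjusted p = 6.40e-12; adjusted p = 0.166 with an estimated correlation). Of 30 glutathione and redox genes, 2 were higher, 0 lower and 28 not called, or 11 higher over the list alone (camera adjusted p = 5.72e-06; adjusted p = 0.338 with an estimated correlation). They were PER1 (GRMZM2G129761), a seed peroxiredoxin (6.74, SE 1.07, adjusted p = 0.0158), and the glutathione S-transferase gst1 (GRMZM2G116273; 3.18, SE 0.51, adjusted p = 0.0171). Of 7 late embryogenesis abundant genes, 2 were higher, 0 lower and 5 not called, or 3 higher over the list alone (camera adjusted p = 3.64e-04; adjusted p = 0.321 with an estimated correlation). They were dhn1 (GRMZM2G079440), a dehydrin, with a ratio of 131 (44.5 to 635, adjusted p = 0.0394), and mlg3 (GRMZM2G096475), with a ratio of 539 (96.6 to 21318, adjusted p = 0.0138). PER1 (adjusted p = 0.143), gst1 (0.130), dhn1 (0.260) and mlg3 (0.150) were not called without starchy endosperm at 18 DAP replicate 2.

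**Figure D2:**
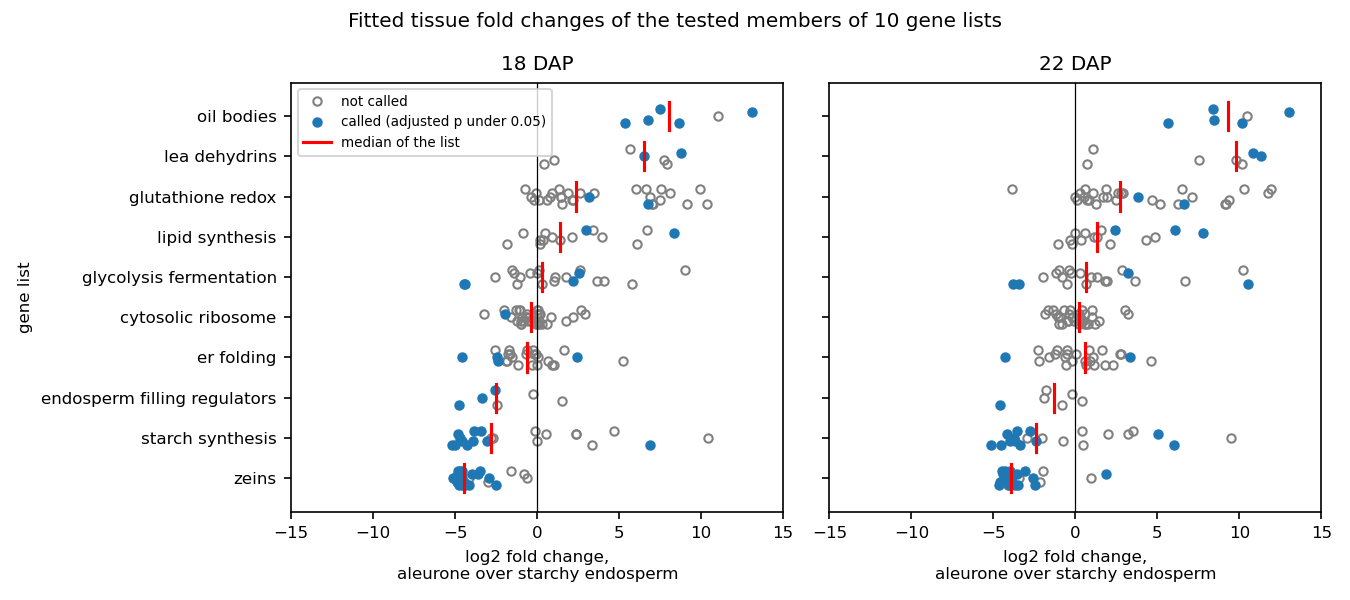
Log2 fold changes of aleurone over starchy endosperm for the tested members of 10 gene lists at 18 and 22 DAP. Each point is 1 gene, blue where called, and red lines are list medians (zeins -4.48 and -3.94); the points farthest right include genes without a count in starchy endosperm, whose fitted value depends on a prior count.

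Some lists carried few called genes. Of 15 lipid synthesis genes, 2 were higher, 0 lower and 13 not called, or 5 higher over the list alone (camera adjusted p = 0.00331; adjusted p = 0.161 with an estimated correlation). These were the desaturase fad7 (GRMZM2G128971; ratio 467, 129 to 3861) and ACC1 (GRMZM5G858094), an acetyl-CoA carboxylase (2.95, SE 0.49). The list was not called without aleurone at 22 DAP replicate 1 (adjusted p = 0.0629) or starchy endosperm at 18 DAP replicate 1 (0.103). Among 31 jasmonate genes, aoc1 (GRMZM2G077316), an allene oxide cyclase, was higher (8.12, SE 1.52, adjusted p = 0.0326), 0 were lower and 30 were not called, also over the list alone (camera adjusted p = 0.0222; adjusted p = 0.568 with an estimated correlation). That call was lost without aleurone at 18 DAP replicate 2 (adjusted p = 0.0539), starchy endosperm at 18 DAP replicate 1 (0.264) or starchy endosperm at 22 DAP replicate 1 (0.0601), and with library size only (0.0558). None of 33 auxin genes was called, also over the list alone (camera adjusted p = 0.00838, toward aleurone; adjusted p = 0.401 with an estimated correlation; 0.131 without starchy endosperm at 18 DAP replicate 1).

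A further 4 lists lay toward starchy endosperm relative to all genes. Of 6 regulators of endosperm filling, 3 were lower in aleurone, 0 higher and 3 not called, or 4 lower over the list alone (camera adjusted p = 3.06e-06; adjusted p = 0.0839 with an estimated correlation). Of 25 genes of protein folding in the endoplasmic reticulum, 3 were lower, 1 higher and 21 not called, or 7 lower and 2 higher over the list alone (camera adjusted p = 3.64e-04; adjusted p = 0.338 with an estimated correlation). The lower ones were fl2, which is itself a zein, PDIL5-1 (-2.39, SE 0.46) and der2 (-2.45, SE 0.42), and the higher one was the disulfide isomerase pdi2 (GRMZM2G163421; 2.42, SE 0.50). The call of pdi2 was lost in 6 of the 8 fits with 1 library left out, and those of PDIL5-1 and der2 in 4 each. Of 37 cytosolic ribosomal proteins only rps27 (GRMZM2G066222) was called, lower at -1.96 (SE 0.35, adjusted p = 0.0277), also over the list alone (camera adjusted p = 0.00108; adjusted p = 0.483 with an estimated correlation). The sign of rps27 reversed in both limma fits, and its call was lost in 4 of the 8 fits with 1 library left out. None of 14 heat shock genes was called, with 3 lower over the list alone (camera adjusted p = 0.0118; adjusted p = 0.511 with an estimated correlation). The median log2 fold changes of the folding, ribosomal and heat shock lists were -0.64, -0.36 and -0.49, and turned to 1.05, 1.27 and 1.13 with library size only, where these lists were not called (adjusted p = 0.103, 0.714 and 0.0526). Heat shock genes were also not called without aleurone at 18 DAP replicate 1 (adjusted p = 0.123), aleurone at 22 DAP replicate 1 (0.0629) or starchy endosperm at 18 DAP replicate 2 (0.125).

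Glycolysis and fermentation genes were not called as a list (21 genes, camera adjusted p = 0.464), with 2 higher, 2 lower and 17 not called, or 7 higher and 6 lower over the list alone. The called ones encode cytosolic glyceraldehyde-3-phosphate dehydrogenases. GPC1 (GRMZM2G046804; 2.52, SE 0.46, adjusted p = 0.0303) and gpc2 (GRMZM2G180625; 2.16, SE 0.42, adjusted p = 0.0385) were higher in aleurone. The isoforms gpc3 (GRMZM2G071630; -4.43, SE 0.51, adjusted p = 0.00425) and gpc4 (GRMZM2G176307; -4.48, SE 0.36, adjusted p = 0.00189) were lower. Defense genes were not called as a list either (17 genes, camera adjusted p = 0.189), with 2 higher (Zlp and cystatin4), 1 lower (cystatin6) and 14 not called, or 5 higher and 2 lower over the list alone. The gene cystatin4 (GRMZM2G013461) was at 3.20 (SE 0.61, adjusted p = 0.0360) and cystatin6 (GRMZM2G401328) at -5.98 (SE 0.99, adjusted p = 0.0185). GPC1 was not called without starchy endosperm at 18 DAP replicate 2 (adjusted p = 0.242).

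To assess the same tissue difference at 22 DAP, both tissues were compared at the later age. Oil storage genes were again higher in aleurone, with ole1 at a log2 fold change of 8.38 (SE 1.02, adjusted p = 0.00665) and 6133 ± 4757 against 5.30 ± 1.17 TPM, and ole17 at 10.19 (adjusted p = 0.00667). The further oleosin was at least 389-fold higher (adjusted p = 0.00704). The starch genes sh1 (-3.72, SE 0.46, adjusted p = 0.00665), sh2 (-4.55, SE 0.54, adjusted p = 0.00598) and bt2 (-5.15, SE 0.66, adjusted p = 0.00820) were lower in aleurone. The sucrose synthase sus1 was higher (6.02, SE 0.58, adjusted p = 0.00301), and so was sus2 (5.01, SE 0.93, adjusted p = 0.0364).

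In all 322 genes were called at 22 DAP, 226 higher and 96 lower in aleurone, each with the same sign in both replicate numbers, which their selection again favors. Over all tested genes, the tissue differences of the replicate numbers correlated at r = 0.49. The replicate block gave 580 (327 higher and 253 lower), upper quartile factors gave 467 (247 and 220) and library size only gave 1623 (1585 and 38). A fit of only the libraries compared called 0 genes, DESeq2 called 2360, and 3090 genes had an unadjusted p under 0.05 in the edgeR fit of all libraries. Without starchy endosperm at 22 DAP replicate 1 the count was 4938, and without aleurone at 22 DAP replicate 2 it was 179.

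Other genes without a count in starchy endosperm at this age were AD1 (GRMZM2G167438), at least 151-fold higher in aleurone (adjusted p = 0.00823), dxs2 (at least 160-fold, adjusted p = 0.0309), the beta-expansin expB3 (GRMZM2G474194; at least 120-fold, adjusted p = 0.0183) and the homeodomain gene ocl1 (GRMZM2G026643; at least 119-fold, adjusted p = 0.0176). The glycolytic enzyme enolase (GRMZM2G009030) was at least 62.7-fold higher (adjusted p = 0.0425). GPC1 (3.19, SE 0.48, adjusted p = 0.0163), gpc3 (-3.78, SE 0.49, adjusted p = 0.00903) and gpc4 (-3.41, SE 0.34, adjusted p = 0.00351) kept their sides, and gpc2 was not called (1.91, adjusted p = 0.0654). Calls of the 35 named genes were fewest without aleurone at 22 DAP replicate 2 or starchy endosperm at 22 DAP replicate 2, at 25 each. Among the 10 lost without the first were enolase (adjusted p = 0.119), expB3 (0.109), pdi2 (0.108), dhn1 (0.0763), mlg3 (0.0649), ocl1 (0.0647) and dxs2. Among the 10 lost without the second were dxs2 (0.0890), PER1 (0.0849), GPC1 (0.0614), Zlp (0.0614), enolase and pdi2.

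At 22 DAP, 20 of 26 zeins were lower in aleurone, 1 was higher and 5 were not called, or 23 lower and 1 higher over the list alone (camera adjusted p = 8.10e-71; adjusted p = 0.0367 with an estimated correlation, and 0.102 with that and the replicate block). The alpha-zein z1A1_3 was at -4.50 (SE 0.42, adjusted p = 0.00301) and fl4 (GRMZM2G353272) at -4.25 (SE 0.40, adjusted p = 0.00301). The higher zein was az22z5 (GRMZM2G088365; 1.87, SE 0.37, adjusted p = 0.0452). Among 21 starch synthesis genes the same 10 were lower, 2 were higher (sus1 and sus2) and 9 were not called, or 11 lower and 4 higher over the list alone (camera adjusted p = 1.30e-09; adjusted p = 0.196 with an estimated correlation). Of the 6 regulators of endosperm filling, 1 was lower (fl3), 0 higher and 5 not called, or 3 lower over the list alone (camera adjusted p = 6.65e-06; adjusted p = 0.0935 with an estimated correlation). Their median of -1.31 turned to 0.16 with library size only.

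Toward aleurone, 5 of 6 oil body genes were higher, 0 lower and 1 not called, or 6 higher over the list alone (camera adjusted p = 4.79e-11; adjusted p = 0.240 with an estimated correlation). Of 30 glutathione and redox genes, 2 were higher, 0 lower and 28 not called, or 13 higher over the list alone (camera adjusted p = 8.21e-05; adjusted p = 0.465 with an estimated correlation), with gst1 at 3.82 (SE 0.53, adjusted p = 0.0120) and PER1 at 6.60 (SE 1.08, adjusted p = 0.0218). Of 7 late embryogenesis abundant genes, dhn1 (at least 116-fold) and mlg3 (at least 84.0-fold) were higher, 0 lower and 5 not called, or 4 higher over the list alone (camera adjusted p = 5.22e-04; adjusted p = 0.339 with an estimated correlation). Both of these lists missed the threshold without starchy endosperm at 22 DAP replicate 1 (adjusted p = 0.0577 each). None of 37 cytosolic ribosomal proteins was called, also over the list alone, while the list lay below all other genes (median 0.22, camera adjusted p = 0.0200; adjusted p = 0.570 with an estimated correlation). Its median was -0.19 with upper quartile factors, and the list was not called without aleurone at 22 DAP replicate 1 (adjusted p = 0.0576) or starchy endosperm at 22 DAP replicate 2 (0.0679), or with library size only (0.275).

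Lipid synthesis, defense and protein folding genes were not called as lists at 22 DAP (camera adjusted p = 0.0514, 0.0514 and 0.0709), while the replicate block gave adjusted p = 0.0345, 0.0136 and 0.0318 (0.392, 0.541 and 0.541 with an estimated correlation as well). The first 2 lists lay toward aleurone relative to all genes and the folding list toward starchy endosperm. Of 15 lipid genes, 3 were higher, 0 lower and 12 not called, or 4 higher over the list alone, and of 17 defense genes, 2, 0 and 15, or 5 higher and 1 lower over the list alone. Of 25 folding genes, 1 was higher, 1 lower and 23 not called, or 3 higher and 5 lower over the list alone. Higher in aleurone were the desaturases fad7 (ratio 304, adjusted p = 0.0439, and 0.0523 with the replicate block) and fad2 (GRMZM2G064701; 6.06, SE 1.16, adjusted p = 0.0406), ACC1 (2.41, SE 0.48, adjusted p = 0.0469), cystatin4 (3.65, SE 0.63, adjusted p = 0.0266), Zlp (adjusted p = 0.0120) and pdi2 (3.34, SE 0.53, adjusted p = 0.0193), and lower was fl2 (-4.28, SE 0.42, adjusted p = 0.00323). Without aleurone at 22 DAP replicate 2, fad7 (adjusted p = 0.0973), fad2 (0.112), cystatin4 (0.0801) and pdi2 (0.108) were not called. The call of ACC1 was lost in 5 of the 8 fits with 1 library left out, up to adjusted p = 0.145 without aleurone at 22 DAP replicate 1.

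Across all 19058 genes, tissue log2 fold changes at both ages, which share no library, correlated with r = 0.66 (rho = 0.65). The value was 0.37 without starchy endosperm at 22 DAP replicate 1, 0.73 in replicate 1 libraries alone and 0.41 in replicate 2 libraries alone. Higher in aleurone at both ages were 174 genes, among them ole1, ole17, sus1 and gst1, against 2.73 for independent lists, and 89 were lower at both ages, among them bt2, sh2 and fl3, against 0.831. Independent lists are a low mark here, since both contrasts came from 1 fit with 1 filter and 1 estimate of each gene's spread. Of genes called at either age, 280 of 282 on the aleurone side and 172 of 172 on the starchy endosperm side had the same sign at the other age. These counts include the genes called at both ages, whose signs agree by the way they were counted. The median gene was shifted toward aleurone by 0.47 at 18 DAP and 0.94 at 22 DAP, and with library size only by 2.14 and 2.56. With 1 library left out it ranged from 0.25 to 1.09 at 18 DAP, and at 22 DAP from 0.58 to 5.38, the last without starchy endosperm at 22 DAP replicate 1.

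Classical regulators varied in their tissue contrast. The regulators of zein genes o2 (GRMZM2G015534), a bZIP factor, and pbf1 (GRMZM2G146283), a DOF factor, were lower in aleurone at 18 DAP, at -3.36 (SE 0.51, adjusted p = 0.0133) and -2.60 (SE 0.53, adjusted p = 0.0443). Without starchy endosperm at 18 DAP replicate 2 o2 was not called (adjusted p = 0.123), and pbf1 reached adjusted p = 0.358 with 1 library left out. At 22 DAP o2 was at -1.93 (SE 0.48, adjusted p = 0.101, and 0.0114 with the replicate block) and pbf1 at -1.78 (adjusted p = 0.149). The PLATZ protein gene fl3 (GRMZM2G006585) was lower at both ages, at -4.77 (SE 0.44, adjusted p = 0.00196) and -4.60 (SE 0.44, adjusted p = 0.00301). Opaque11 was at -2.47 at 18 DAP (adjusted p = 0.238, and 0.0462 with the replicate block).

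Of the genes of aleurone fate, vp1 was called at 18 DAP and at 22 DAP had a lower bound of 96.0-fold (adjusted p = 0.0536, and 0.0404 with the replicate block). The paralogs nkd1 (GRMZM2G129261) and nkd2 (GRMZM5G884137), zinc finger factors, were at 0.12 and 0.11 at 18 DAP (adjusted p = 0.971 and 0.978) and at 1.55 and 0.82 at 22 DAP (adjusted p = 0.207 and 0.533). In TPM nkd1 was 74.3 ± 0.849 in aleurone and 16.3 ± 1.26 in starchy endosperm at 18 DAP. TPM are not TMM-scaled, and the median gene at 18 DAP lay at 0.47 with TMM and at 2.14 with library size only. Whether the nkd genes differed between the tissues thus depends on the scaling. The receptor kinase cr4 was at 2.45 at 18 DAP (adjusted p = 0.471), and dek1 and sal1 were at -0.49 and 0.49 (adjusted p = 0.853 and 0.882). As a list, aleurone regulators were not called at either age (camera adjusted p = 0.460 and 0.243).

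**Figure D3:**
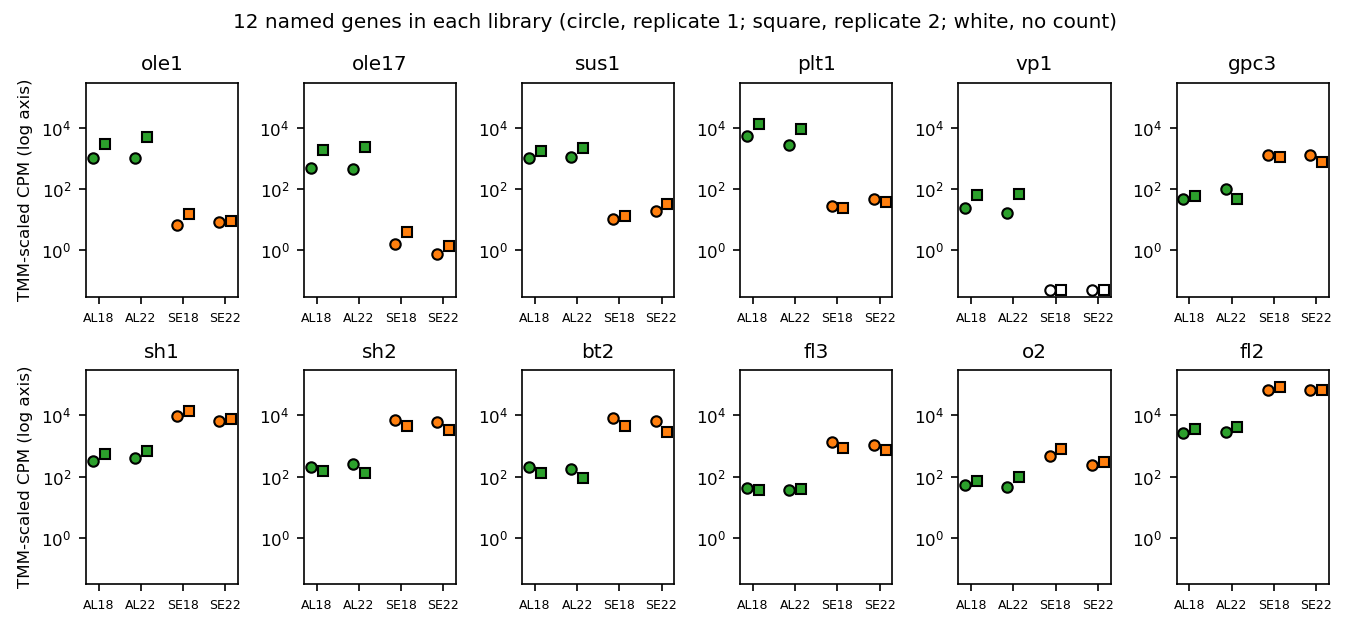
TMM-scaled CPM on a log axis for 12 genes in each of the 8 libraries, by tissue and age: ole1, ole17, sus1, plt1, vp1, gpc3, sh1, sh2, bt2, fl3, o2 and fl2. Each point is 1 library and white points mark libraries without a count; log2 fold changes of ole1, for example, were 7.46 and 8.38.

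To assess how aleurone changed with age, peels at 22 DAP were compared with peels at 18 DAP. Genes of anthocyanin synthesis were detected mainly in the older peels: fht1 (GRMZM2G062396) was at 22.8 ± 1.2 TPM at 22 DAP and without a count at 18 DAP (ratio at least 109), and a1 (GRMZM2G026930) was at 32.6 ± 1.68 against 0.160 ± 0.226 TPM. No gene was called by edgeR (adjusted p = 1 for both), with 196 at an unadjusted p under 0.05. That is below the share of 0.05 among 19058 tested genes due without any change, so the 0 calls may reflect a cautious test. DESeq2 called 3 genes, neither fht1 nor a1 among them, and limma on log2(TPM + 1) called 25, with a1 and fht1 (adjusted p = 0.0197 each). Of the 26 called by limma on log2(TPM + 0.1), fht1 was 1 (0.0403) and a1 was not. The gene GRMZM2G061303, lower in the older peels, was called by DESeq2 (adjusted p = 4.23e-05), in both limma fits (0.0197 and 0.0403) and without a filter. All 5 tested anthocyanin genes lay above 0, and the list was called (camera adjusted p = 9.80e-08; adjusted p = 0.432 with an estimated correlation), with 0 members called over all genes and 2, fht1 and a1, over the list alone. By fry it was not called (adjusted p = 0.383). The floral regulators listed as pericarp markers were also higher in these older peels (130 ± 18.1 against 53.9 ± 3.72 TPM).

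A further 5 lists were higher in the older aleurone by camera, with 0 members called over all genes or over the list alone in each. They were cytosolic ribosomal proteins (33 of 37 above 0, median 0.38, adjusted p = 3.34e-05), floral and pericarp markers (5 of 6, adjusted p = 0.00635), defense genes (12 of 17, adjusted p = 0.0113), aquaporins (12 of 16, adjusted p = 0.0113) and zeins (21 of 26, median 0.36, adjusted p = 0.0180). With an estimated correlation the adjusted p was 0.475 for the floral markers and 0.918 for ribosomal proteins, defense genes, aquaporins and zeins, and by fry it was 0.972 for all 5. The cystatin gene cystatin7 (GRMZM2G148925) of the defense list was at 105 ± 9.55 TPM at 18 DAP and 426 ± 108 TPM at 22 DAP, and the floral gene zag3 had a ratio of 40.5 (13.5 to 199). Without aleurone at 18 DAP replicate 1 none of the 5 was called (ribosomal 0.221, floral 0.184, defense 0.513, aquaporins 0.276, zeins 0.526). Without aleurone at 22 DAP replicate 2 the defense (0.847), aquaporin (0.557) and zein (0.137) lists were not called, without aleurone at 22 DAP replicate 1 the floral list was not (0.130), and without starchy endosperm at 22 DAP replicate 2 zeins were not (0.103). Histones were added by the replicate block (adjusted p = 0.0209, and 0.667 with an estimated correlation as well).

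To assess how starchy endosperm changed with age, the same comparison was made in the inner tissue. Some chaperone genes of the endoplasmic reticulum had lower fitted values at 22 DAP, though none was called by edgeR: bip2 (GRMZM2G415007) at -4.59 (SE 0.69, adjusted p = 0.669), bip1 (GRMZM2G114793) at -2.04 (SE 0.63) and the calnexin gene CNX at -1.63 (SE 0.40). In TPM bip1 was 142 ± 58.8 at 18 DAP and 37.2 ± 28.7 at 22 DAP. In the other direction, aoc1 was at 4.84. The ZCN10 genes GRMZM2G152689 and GRMZM2G059358 had fitted values of 6.70 and 6.68. Neither had a count in starchy endosperm at 18 DAP, so these values depend on a prior count and could not have pointed to a fall. Like aoc1, the ZCN10 genes had been called higher in aleurone at 18 DAP. No gene was called by edgeR, with 655 at an unadjusted p under 0.05, again below the share of 0.05 due without any change. DESeq2 called 32, among them bip2 (-4.54, adjusted p = 8.80e-06). Without starchy endosperm at 22 DAP replicate 1, the library with more detected genes, 3166 genes were called, 145 higher and 3021 lower at 22 DAP.

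The lists of protein folding (25 genes, median -0.71) and heat shock (14 genes, median -1.60) were lower at 22 DAP in starchy endosperm (camera adjusted p = 0.0103 each; adjusted p = 0.972 with an estimated correlation and 0.421 by fry), with 0 members called over all genes and 2 folding genes lower over the list alone. Cytosolic Hsp70 was at -1.53 (SE 0.67) and HSP90-2 at -0.97 (SE 0.44). Folding genes were not called without starchy endosperm at 18 DAP replicate 1 (adjusted p = 0.474), heat shock genes without starchy endosperm at 18 DAP replicate 2 (0.299), and neither without starchy endosperm at 22 DAP replicate 1 (0.303 and 0.397). Age differences in the tissues were nearly uncorrelated across genes (r = 0.07, rho = 0.10). Between the replicate numbers of 1 tissue, age differences correlated at r = 0.36 in aleurone and 0.075 in starchy endosperm. The low value between tissues therefore does not show that they aged differently.

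To assess whether the tissue difference itself changed between the ages, the interaction was tested. The tissue difference of bip2 shifted toward aleurone by a fitted log2 of 4.56 (SE 0.88) and that of o2 by 1.44 (SE 0.66). No gene was called by edgeR (adjusted p = 1 for both), with 390 at an unadjusted p under 0.05, again below the share of 0.05 due without any change. DESeq2 called 7, among them bip2 (4.47, adjusted p = 0.0490). Without starchy endosperm at 22 DAP replicate 1, 2260 genes were called. No list was called, the lowest being heat shock (camera adjusted p = 0.186) and protein folding (0.211), while the replicate block gave adjusted p = 0.0260 for both and 0.00660 for zeins (0.423 without it). With the block and an estimated correlation, the adjusted p was 0.898 for each of these 3 lists.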

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

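Directions of called genes held in all fits but limma, where 4 genes changed sign at 18 DAP and 2 at 22 DAP, while counts of calls varied. In the tissue contrast at 18 DAP, 395 genes were called, against 1332 with library size only, 593 with upper quartile factors, 1215 without a filter, 2221 with DESeq2, 9576 and 6201 with limma on log2(TPM + 1) and log2(TPM + 0.1), 747 in a fit of only the libraries compared, 808 with the replicate block, 758 with the replicate block within age, and 1498 without both starchy endosperm libraries of 22 DAP, a fit added after the data were seen. At 22 DAP, 322 were called, against 1623, 467, 1266, 2360, 10620 and 8644 in the same order, 0 with only the libraries compared, 580 and 603 with the blocks, and 239 without both starchy endosperm libraries of 18 DAP. DESeq2 called all 395 and all 322 with the same sign, and the replicate block kept 388 and 306. With library size only 281 and 264 were kept. For aleurone with age, 0 genes were called, against 6 without a filter, 3 with DESeq2, and 25 and 26 with limma. For starchy endosperm with age the 0 became 62 without a filter and 32 with DESeq2, and for the interaction 17 and 7. Leaving out 1 library moved the tissue counts from 47 to 1649 at 18 DAP and from 179 to 4938 at 22 DAP, the age count in starchy endosperm from 0 to 3166, the interaction from 0 to 2260, and the correlation of tissue differences from 0.37 to 0.62. Most of the upper ends came without starchy endosperm at 22 DAP replicate 1, after which 1 library with 9335 detected genes stood for its group. Of 125 list tests 27 were called, and 2 with an estimated correlation, zeins at each age (adjusted p = 0.0220 and 0.0367). With the replicate block and an estimated correlation 0 were called, and zeins were at 0.220 and 0.102. Fry called 9, 17, 0, 0 and 0 lists in the 5 contrasts (tissue at 18 and 22 DAP, age in aleurone and in starchy endosperm, and interaction), against 12, 7, 6, 2 and 0 by camera, and kept 14 of the 27. Lost at 18 DAP were protein folding (fry adjusted p = 0.130), ribosomal proteins (0.193), heat shock (0.272) and jasmonate (0.0503), and at 22 DAP ribosomal proteins (0.961). The gene rps27 reversed at 18 DAP, at 0.12 in both limma fits (adjusted p = 0.711 and 0.642). The causes of these differences were not tested. Apart from the values given beside the results, the replicate block changed no list call at the preset correlation, and of the named genes only fad7 at 22 DAP was lost with it (adjusted p = 0.0523). In simulated counts, which lacked a gene-specific spread and an effect of the replicate number, 16-fold changes were recovered in 38% to 49% of the changed genes in the contrasts of groups.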

Other observations

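Genes described in this paragraph were picked after the values were seen, from 5 families looked at, so their adjusted p-values describe and do not test the families. Sucrose synthases are given with the tissue contrasts, and a set named AR1 to AR7 was left out because the name does not say what the genes encode. Besides HDZIV8_OCL8, the homeodomain gene ocl1 was called at both ages (edgeR adjusted p = 0.0163 and 0.0176), and ocl5 (GRMZM2G130442) at 18 DAP only (0.0446, and 0.0570 at 22 DAP). In the same family HDZIV6_OCL6 (0.0651 and 0.0616) and ocl4 (0.308 and 0.321) were not called. Of 4 asparagine synthetases, asn2 (GRMZM2G093175) was higher in aleurone (adjusted p = 0.00638 at 18 DAP; log2 fold change 6.03, SE 0.95, adjusted p = 0.0188 at 22 DAP) and Asn1 (GRMZM2G154182) was lower (-4.08, SE 0.41, adjusted p = 0.00234, and -2.90, SE 0.39, adjusted p = 0.0104). The others, asn1 (GRMZM2G074589; adjusted p = 1 and 0.447) and asn3 (GRMZM2G053669; 0.976 and 0.792), were not called at 18 or 22 DAP. The inositol phosphate synthases INO1 (GRMZM2G155242) and mips2 (GRMZM2G004528), at the first step of inositol and phytate synthesis, were higher in aleurone at 22 DAP (6.63, SE 1.16, adjusted p = 0.0279, and 6.54, SE 1.18, adjusted p = 0.0319). At 18 DAP they were at 4.88 (adjusted p = 0.0533) and 3.60 (adjusted p = 0.111).

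Of the tests below, only that of gene length was chosen before its result was seen, and the other 3 were chosen afterwards. In every group the replicate 2 library held more counts but fewer detected genes than replicate 1, and of genes due 20 to 99 counts by their share in replicate 1, 8.39% to 43.3% had none in replicate 2 (0.660% to 3.60% the other way). Uptake of reads by zeins and the most abundant genes could not account for this, since the counts left after removing them were at least 2.01 times higher in replicate 2. Gene length was set aside as the whole cause, as genes missed in replicate 2 had a median length of 0.969, 1.02, 1.03 and 1.07 times that of genes found in both, although longer genes were slightly lower in replicate 2 in all groups (rho from -0.108 to -0.177). Many reads from few molecules stays open: at most 10.98% of detected genes in a replicate 2 library had 1 to 9 counts, against 27.8% to 45.0% in replicate 1, but more counts over fewer genes lower this share by themselves. The amount of RNA, the library preparation and the plants cannot be told apart here, and no biological explanation was tested.

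Some abundant genes of starchy endosperm were compared with the zeins in the peels: those of at least 200 CPM there with a log2 fold change under -3, members of the zein list left out. Genes without a name were not in that list, so zeins may remain among the genes compared. Of 64 such genes at 18 DAP, 0 lay by more than 2 SE below the median of the 19 zeins in the same range (-4.59), and 1 of 34 did at 22 DAP (median -4.10), at most 2.94%, with the lowest gene at -6.16 and -5.51, while 60.2% and 61.3% of the genes as far higher in aleurone lay beyond the mirrored marks. Less abundant called genes were lower in aleurone by a log2 of up to 7.13 and 8.61, so this holds for the abundant genes only. The comparison was prompted by the values it measures, so it does not support starchy endosperm RNA carried into the peels, which stays open beside expression of zeins and starch genes in aleurone cells, and that was not tested.

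The deposited table of mean TPM listed 4807, 5565, 6385 and 8799 genes at 0 that were above 0 in 1 of the libraries (aleurone at 18 and 22 DAP, starchy endosperm at 18 and 22 DAP). They held 0.992%, 1.03%, 0.634% and 1.38% of TPM, and in each case the other library of the group was at 0. With such genes set to 0 and each library rescaled, 100% of the listed means above 0 were rebuilt to within 0.1%. The globulin genes, summed, were at 607 and 2303 TPM in aleurone at 18 DAP replicates 1 and 2, and at 331 and 2159 TPM in starchy endosperm. The gene GRMZM5G892124, which had no name, was the most abundant of all genes in aleurone at 22 DAP, at 34301 ± 248 TPM. At 18 DAP it was at 12539 ± 1817 TPM in aleurone. In starchy endosperm at 22 DAP its mean was 961 TPM, with 1 library at 0.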
